A study of Mus musculus with 26 samples.

How the data were processed

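Microglia were sorted by flow cytometry (FACS AriaIII) as EGFP-positive cells from CX3CR1-EGFP mice on a C57BL/6 background, per the labels' protocols. The tissue was a 1.5 mm punch of the medial prefrontal cortex (mPFC) or the nucleus accumbens (NAc), and each sample pooled 3 to 6 mice. Mice were perfused 1.5 hours following their final exposure to repeated social defeat stress (R-SDS), in which a mouse meets an aggressive mouse, or to a transfer between cages (naive). From 500 pg of RNA, cDNA was made with the Ovation amplification kit, labelled with Cy3 and hybridised to a single-colour Agilent mouse array, per the labels' protocols. The labels call the stressed wild-type mice susceptible and the stressed TLR-DKO mice resilient, and say that the samples come from 2 independent experiments with different mice.

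The deposited scanner files hold spot intensity values on a linear scale, made with Agilent Feature Extraction 11.0.1.1 per the file headers, already background-subtracted in the processed signal. Each array has 62976 spots, of which 59305 are not controls and carry 55681 probes. The deposited matrix of values holds log2 values of 55821 probes whose scale, centring and direction the labels do not state. Its columns had a Pearson r of 1 with the scanner values of the same array across probes and differed by a constant of at most 0.062, so it is log2 of the processed signal minus about the 75th percentile. Its column medians ran from -2.90 to -2.21.

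For this work, log2 of the processed signal minus the array's 75th percentile of it was the measured value, and spots of one probe were averaged. Control spots and spots marked as outliers were left out, which removed 108 probes, and 0 spots were saturated. The scanner files hold no column of gene names, so probes were named from their accession through a RefSeq table of assembly GRCm38.p6. Of 29796 probes with a RefSeq-style accession, 28026 matched, and the other 27655 probes keep the name in the file. The file headers name build mm9, so no coordinates are printed and the RefSeq table served only for names and for the order of neighbouring genes.

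The array's brightness limits the precision of dim probes. The 75th percentile of the processed signal ran from 80.7 units (wild-type mPFC R-SDS replicate 3) to 340.5 units (wild-type mPFC naive replicate 3). The share of spots well above background ran from 50.0% (TLR-DKO NAc naive replicate 3) to 71.0%. A probe was tested where it was well above background on at least 3 arrays of at least 1 group, and the probe with the highest mean over all arrays stood for its gene. This left 24739 genes, of which 13556 were named through RefSeq. The median SD between arrays of a group was 0.76 on the log2 scale.

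All 26 arrays were fitted together as 8 group means with limma 3.58.1 (lmFit and eBayes, two-sided, R 4.3.3), and p was adjusted by Benjamini-Hochberg with a threshold of 0.05. Folds of genes not well above background on any array of a group are bounds, computed against the higher of the array's lowest signal well above background and the gene's own signal. Such a bound ("at least") allows for background only and holds no sampling error, so it is not a confidence limit. The samples lie on 4 slides, 2 of each region, and were scanned on 2 days with 1 slide of each region on each day. Each slide holds several groups, so slide as a block and each slide alone were run for the comparisons within a region. A slide alone often leaves 1 array in a group, as on slide 2, which holds only replicate 3 of each wild-type mPFC group. Within any slide alone even Tlr2, a targeted gene, missed the threshold between naive genotypes, so counts of 0 genes there say nothing. For the region effect, where a slide holds a single region, slide was a random block with an estimated consensus correlation of 0.137.

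The design, the test, the comparisons, the gene lists and most alternatives were chosen before the data were examined. Chosen after seeing the data were the averages over both regions, the scan day as a block or alone, the counts over named genes only, the fits without 2 outlying arrays (wild-type mPFC R-SDS replicate 3 and TLR-DKO mPFC naive replicate 1, with array weights of 0.25 and 0.47), and gMedianSignal in place of gMeanSignal, a column that was not used here. The alternatives covered background correction (normexp with an offset of 50), normalization, the filter on dim probes, probes of a gene, the variance estimate, array weights, the deposited matrix, the samples in the fit, slide, replicate numbers and leaving out each array in turn.

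The 29 gene lists held 16 pathways or states and 13 sets of markers of cells that the gate or the punch could hold, with 488 of 584 symbols measured. The 26 lists with at least 5 members measured were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Members of a list were also adjusted over the list alone. Erythroid, neutrophil and oligodendrocyte precursor markers had 4, 4 and 2 members measured and were not tested. The genes named are, for each comparison, up to 12 in each direction with the largest change among those past the threshold whose groups did not overlap, filled with the smallest unadjusted p, of which a part is described, together with Tlr2, Tlr4, Cx3cr1, Il1a, Tnf and up to 4 members of a described list. Clone and transcript identifiers are counted, and the single one that is named was chosen after its values were seen.

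The procedure was tested on simulated data with 200 of 24739 genes changed. For the stress effect in wild-type mPFC it recovered 0%, 38.8% and 69.7% of genes changed by 1, 2 and 4 on the log2 scale, with 6 false calls. The stress effect in TLR-DKO NAc gave 0%, 31.3% and 75.8%, with 4 false calls, and the mPFC interaction 0%, 2.99% and 54.5%, with 2 false calls. The region effect gave 31.3%, 70.1% and 92.4%, with 27 false calls. The slide correlation was estimated at 0.0301 where 0.0826 was simulated, and with the simulated value there were 3 false calls, so in this simulation the low estimate accounts for most of the false calls. A shifted list of 40 genes was found in each, and 0 of 20 unshifted lists were called. The simulated genes varied independently of each other and held no scan day effect. The simulation therefore says nothing about false calls of lists whose genes vary together. Files were read with data.table at version 1.17.8, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.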

Results

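Gene expression was measured in CX3CR1-EGFP-positive microglia sorted from the mPFC or the NAc of wild-type and TLR-DKO mice, after R-SDS or in naive mice. The 26 arrays fall into 8 groups. The mPFC gave 3 wild-type naive, 3 wild-type R-SDS, 4 TLR-DKO naive and 3 TLR-DKO R-SDS samples. The NAc gave 3 wild-type naive, 3 wild-type R-SDS, 3 TLR-DKO naive and 4 TLR-DKO R-SDS samples. Arrays of one group correlated with Pearson r between 0.80 and 0.92 across genes (median 0.87), and the first 2 principal components held 11.2% and 10.3% of the variance. The first followed the scan day, with 13 of 13 arrays of day 1 below 0 and 12 of 13 of day 2 above 0. On the second, wild-type mPFC R-SDS replicate 3 stood apart from all others (-238), and its mean r with the other arrays was 0.79. The number of arrays limits the precision of every value. Levels are log2 signal relative to the array's 75th percentile.

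The targeted genes were examined first. TLR-DKO is not spelled out by the labels and is known from the published study as loss of the innate immune receptors Tlr2 and Tlr4. Tlr2 stood at 1.90 ± 0.60 (SD, n = 3) in naive wild-type mPFC and at 1.93 ± 0.74, 1.89 ± 0.28 and 1.37 ± 0.69 in the other wild-type groups. Tlr2 was not well above background on any of the 14 TLR-DKO arrays. It was at least 50.3-fold lower in naive TLR-DKO mPFC than in wild type, at least 46.8-fold after R-SDS in mPFC, at least 43.2-fold in naive NAc and at least 34.8-fold after R-SDS in NAc. The fitted differences were -5.67 ± 0.38, -5.82 ± 0.41, -5.83 ± 0.41 and -5.61 ± 0.38 (log2, SE), with limma adjusted p of 4.31e-08, 9.29e-08, 9.07e-08 and 5.40e-08. Tlr4 differed by 0.40 ± 0.51, 0.16 ± 0.54, -0.26 ± 0.54 and 0.44 ± 0.51 in the same order, with adjusted p of 0.948 or more. The position of the Tlr4 probe relative to the deleted part is unknown, so its signal checks nothing about the labels. Cx3cr1, the fractalkine receptor gene whose promoter drives EGFP, had group means between 8.25 and 8.69.

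The stress effect in wild-type mPFC compares R-SDS mice, which the labels call susceptible, with naive mice. Immediate early and heat shock genes, which respond quickly to stimulation and protein damage, rose as a list, with 25 of 28 members above 0 and a median log2 change of 1.03 (camera adjusted p = 9.27e-08, adjusted p = 0.219 with an estimated correlation). Among them, the transcription factors Klf4, Atf3, Fos and Junb, which did not pass as genes, stood at 3.18 ± 0.85, 1.81 ± 0.54, 1.84 ± 0.62 and 1.75 ± 0.61 (log2, SE). Glucocorticoid receptor targets were higher as a list, with 17 of 23 members above 0 and a median of 0.59 (camera adjusted p = 0.0177, adjusted p = 0.122 with an estimated correlation). Tsc22d3, which encodes the anti-inflammatory protein GILZ, stood at 1.75 ± 0.46, Ddit4, an inhibitor of mTORC1, at 2.23 ± 0.62, Fkbp5, a co-chaperone of the glucocorticoid receptor, at 1.35 ± 0.49, and the clock gene Per1 at 1.77 ± 0.74, and none of these passed as a gene. Cytokines and chemokines had 16 of 20 members above 0 (median 0.84, camera adjusted p = 0.0266, adjusted p = 0.723 with an estimated correlation), with Cxcl10 at 2.70 ± 0.82, Il1a at 2.16 ± 0.90, Ccl4 at 1.60 ± 0.62 and Ccl3 at 1.47 ± 0.47. NF-kappaB targets and feedback genes had 19 of 25 above 0 (median 0.84, camera adjusted p = 0.0481, adjusted p = 0.906 with an estimated correlation), with Zc3h12a, an RNase that degrades cytokine mRNA, at 2.54 ± 1.08 and Rel, a subunit of NF-kappaB, at 1.94 ± 0.67.

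All 40 cytosolic ribosomal protein genes were above 0, with a median of 0.65 (camera adjusted p = 9.58e-09, adjusted p = 0.723 with an estimated correlation), among them Rps16 at 1.15 and Rpl13 at 1.03. Neuron markers moved with these lists. All 9 measured members were above 0, with a median of 0.94 (camera adjusted p = 0.0481, adjusted p = 0.205 with an estimated correlation), and the neurofilament gene Nefl stood at 4.80 ± 2.43. With an estimated correlation 0 of these 6 lists passed. Of the members, 2 immediate early genes, 2 glucocorticoid receptor targets and 2 cytokines were higher when adjusted over the list alone, and 0 in the other 3 lists. With slide as a block, neuron markers had an adjusted p of 0.0569 and the other 5 lists stayed under 0.05. Within slide 1 and slide 2 the median over all genes was -0.0449 and 0.61, and the mean shift was 0.71 and 1.89 for immediate early genes, 0.57 and 0.82 for glucocorticoid receptor targets, and 0.99 and 1.28 for cytokines. It was 0.62 and 0.81 for NF-kappaB targets and 1.55 and 1.18 for neuron markers. Ribosomal protein genes shifted by 0.046 on slide 1 and by 1.88 on slide 2, and with normexp and quantile normalization their median was 0.23. Without R-SDS replicate 2, the adjusted p rose to 0.27 for glucocorticoid receptor targets, 0.34 for cytokines, 0.45 for NF-kappaB targets and 0.38 for neuron markers.

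The other lists in this comparison had adjusted p of 0.513 or more. Their median log2 changes were 0.38 for phagocytosis and complement, 0.48 for disease-associated microglia, 0.32 for glycolysis and hypoxia, 0.38 for type I interferon response, 0.20 for homeostatic microglia and 0.04 for Toll-like receptor signalling genes. They were 0.32 for antigen presentation, 0.40 for apoptosis and p53, 0.23 for cell cycle, 0.28 for oxidative phosphorylation and 0.05 for prostaglandin genes. Among cell markers they were 0.62 for astrocytes, 0.30 for B cells, -0.02 for cortical neurons, 0.32 for endothelial and mural cells, 0.22 for monocytes, 0.25 for oligodendrocytes, 0.20 for perivascular macrophages, 0.17 for striatal neurons and 0.17 for T and NK cells. The median over all genes was 0.17 here, 0.0276 with quantile normalization and 0.0350 without R-SDS replicate 3, the array that stands apart.

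Of 24739 genes, 2 passed with limma in wild-type mPFC, both higher, and 1459 had an unadjusted p under 0.05 where 1237 are expected by chance. The same 1237 is expected in each comparison below. Leaving out a single array, the count ran from 955 (without R-SDS replicate 3) to 2918 (without R-SDS replicate 2). With only the groups compared it was 936, so no firm excess is shown. Hilpda, a hypoxia-inducible protein of lipid droplets, was at least 99.0-fold higher (8.72 ± 1.41, adjusted p = 0.0495), with 1 other probe at 8.17. Msantd3 was at least 37.1-fold higher (7.27 ± 0.93, adjusted p = 0.00356). Neither was well above background on any naive array. Both passed with slide as a block (adjusted p = 0.0421 and 0.00621) and Klf4 joined them (adjusted p = 0.0421). Within slides 1 and 2, Hilpda changed by 7.67 and 10.82 and Msantd3 by 5.98 and 9.86, where slide 2 holds only replicate 3 of each group. Hilpda missed the threshold without any single one of the 6 arrays (adjusted p from 0.0700 to 0.369), and Msantd3 missed it only without naive replicate 3 (0.0576). Without R-SDS replicate 3 and TLR-DKO mPFC naive replicate 1, the 2 outlying arrays, Hilpda missed it (7.94, adjusted p = 0.0822) and Msantd3 passed (6.27, adjusted p = 0.0455). Hilpda alone missed it with quantile normalization (adjusted p = 0.059, and 0.142 with normexp), median centring (0.0514), series matrix values (0.0511) and only the region (0.795). Both missed it with only the groups compared (0.181 and 0.480) and with the replicate block (0.0895 each). Genes that did not pass included the heat shock co-chaperone Dnajb4 (3.04), the hyaluronan-degrading Cemip (2.75) and the transcription factor Cebpb (1.41 ± 0.37). On the lower side were the antimicrobial ribonuclease Rnase6 (-2.98), the coagulation inhibitor Tfpi (-2.38, other probes -0.44 and -0.17), the myeloid inhibitory receptor Pilra (-2.30, other probes 0.59 and 1.77) and the transcription factor Hhex (-1.74). Their adjusted p was 0.696 or more. Tlr2, Tlr4 and Tnf had values of 0.03, -0.17 and 1.45.

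**Figure D1:**
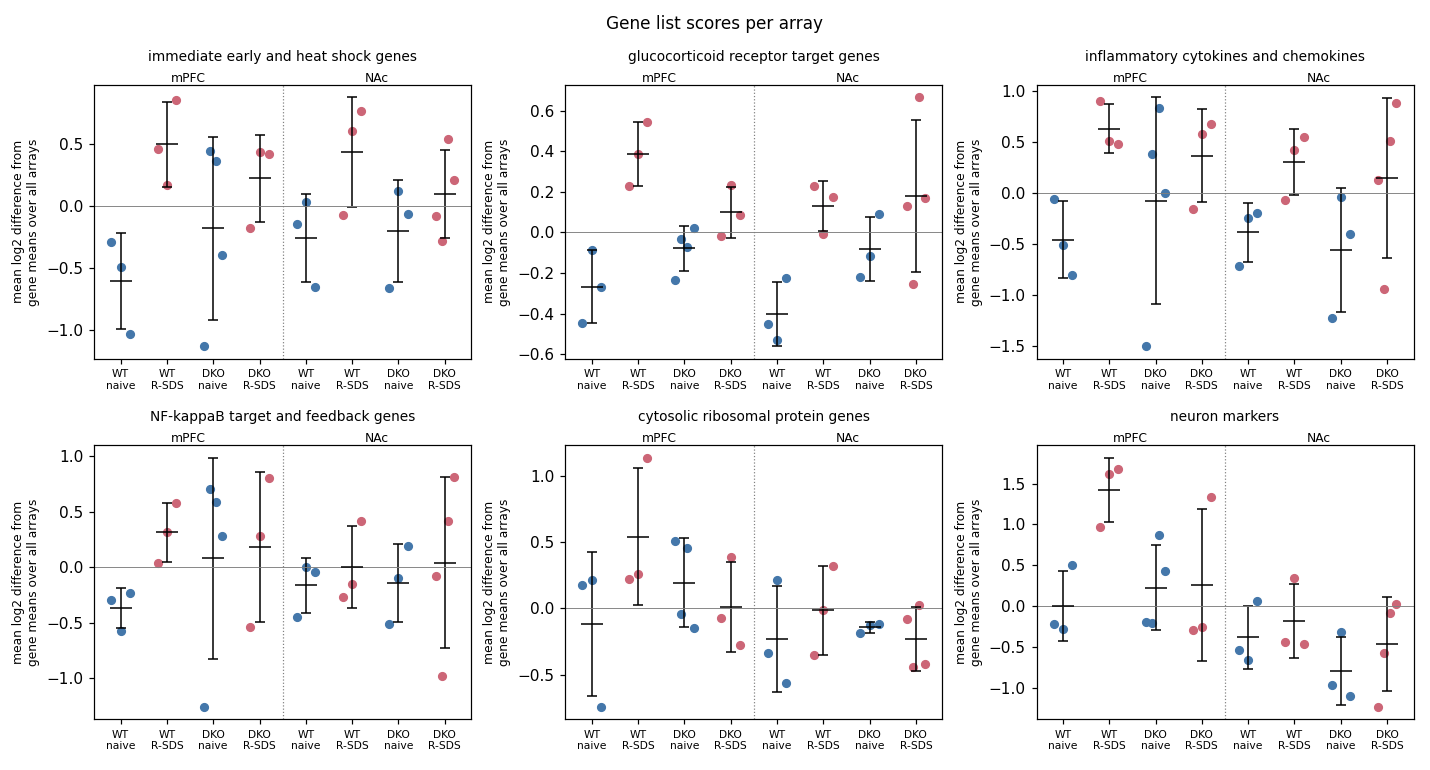
Mean log2 difference of a list's genes from their means over all 26 arrays (y axis) for 6 gene lists in the 8 groups (x axis), with 1 point per array and the mean and SD per group. In wild-type mPFC the mean score of immediate early genes is -0.60 in naive and 0.50 in R-SDS samples, and that of neuron markers is -0.00137 and 1.43.

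The stress effect in TLR-DKO mPFC compares R-SDS mice, which the labels call resilient, with naive mice. Antigen presentation genes were lower as a list, with 6 of 19 members above 0 and a median of -0.49 (camera adjusted p = 0.0417, adjusted p = 0.775 with an estimated correlation). The class II genes H2-Ab1, Cd74 and H2-Eb1 had log2 values of -2.85, -2.73 and -2.17, and the immunoproteasome subunit Psmb8 -1.43. Perivascular macrophage markers moved with them, at a median of -1.20 (adjusted p = 0.111), and 1 of 12 members lay above 0. The lists that passed in wild-type mPFC did not pass here, with medians of 0.22 for immediate early genes (adjusted p = 0.0680), 0.25 for glucocorticoid receptor targets, 0.40 for cytokines, 0.18 for NF-kappaB targets, -0.18 for ribosomal protein genes and -0.18 for neuron markers.

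The mean shift of antigen presentation genes was -1.33 on slide 1 and -0.83 on slide 2, with an adjusted p of 0.0334 with slide as a block, and without naive replicate 1 the adjusted p was 0.22. Adjusted over the list alone 0 members passed. Slide as a block brought immediate early genes (adjusted p = 0.00270), perivascular macrophage markers (0.00270), ribosomal protein genes (0.0116) and NF-kappaB targets (0.0199) past the threshold, and with an estimated correlation and no block 0 lists passed. No gene passed with limma (0 of 24739, smallest adjusted p 0.258), and 1255 had an unadjusted p under 0.05. With slide as a block 0 passed, and with array weights 2 passed. Among named genes the smallest p belonged to Gpcpd1, a phosphodiesterase of choline lipid breakdown (3.54 ± 0.61, at least 7.53-fold), and Cirbp, the cold-inducible RNA-binding protein (-1.99 ± 0.38, adjusted p = 0.275). Noct, a clock-controlled phosphatase, stood at 4.72 ± 1.15 (at least 11.4-fold), lysozyme Lyz1 at -1.59 ± 0.43 and Rnase6 at -2.46 ± 0.68. Gpcpd1 and Noct were not well above background on any naive array, so only these bounds hold for them. Il1a and Tnf had values of -0.13 ± 0.84 and 0.66 ± 1.02.

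The interaction in mPFC tests whether the stress effect differed between genotypes. The labels call the stressed wild-type mice susceptible and the stressed TLR-DKO mice resilient, so genotype cannot be told apart from this outcome. Cytosolic ribosomal protein genes had a lower stress effect in TLR-DKO than in wild type, with 39 of 40 members below 0 and a median difference of -0.86, where the median over all genes was -0.23. Rpl14, Rpl3, Rpl13 and Rps24 differed by -1.51, -1.41, -1.32 and -1.32, of which Rpl14 turned to 0.0158 with the mean of its probes. The camera adjusted p was 1.72e-07, and the adjusted p was 0.725 with an estimated correlation. Immediate early genes, glucocorticoid receptor targets, cytokines and antigen presentation genes had medians of -0.63, -0.39, -0.37 and -0.85 and did not pass in this test (adjusted p of 0.0839, 0.623, 0.583 and 0.0839), so their stress effects are not shown to differ between genotypes. Perivascular macrophage markers had a median of -1.90 (adjusted p = 0.160, 0.0181 with slide as a block, and 0.725 with an estimated correlation and no block). Among genes, 0 passed with limma (0 with slide as a block), and 1507 had an unadjusted p under 0.05. Msantd3 differed by -7.03 ± 1.28 (adjusted p = 0.50), Cirbp by -2.32 ± 0.55 and Il1a, the cytokine interleukin 1 alpha, by -2.29 ± 1.23 (adjusted p = 0.82). The ribosomal difference was -0.40 on slide 1 and -2.25 on slide 2 (median over all genes -0.0931 and -0.73), its median was -0.31 with normexp and quantile normalization, and with slide as a block the adjusted p was 3.44e-11. Adjusted over the list alone 0 ribosomal genes passed.

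The stress effect in wild-type NAc asks whether the accumbens responds to R-SDS. Glucocorticoid receptor targets rose as a list, with 16 of 23 members above 0 and a median of 0.56 (camera adjusted p = 0.00303), and passed with an estimated correlation too (adjusted p = 0.0307). Ddit4 had a log2 value of 2.45 ± 0.62, Tsc22d3 1.77 ± 0.46, the transcription factor Zbtb16 1.72 ± 0.77 (-0.14 within slide 3) and the metallothionein gene Mt1 1.04. Immediate early genes rose as a list too, with 25 of 28 above 0 and a median of 0.67 (camera adjusted p = 4.09e-05, adjusted p = 0.422 with an estimated correlation), among them Egr3 at 2.47, Fos at 1.41 ± 0.62, Fosb at 1.40 and Btg2 at 1.06. Astrocyte markers moved with them, with 11 of 11 above 0 and a median of 0.59 (adjusted p = 0.0584).

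Of the members, 2 glucocorticoid receptor targets and 0 immediate early genes were higher when adjusted over the list alone, and with slide as a block the adjusted p of the lists was 4.68e-04 and 6.68e-08. Slide as a block also brought ribosomal protein genes (adjusted p = 0.00123), cytokines (0.00404), NF-kappaB targets (0.0146) and B cell markers (0.0155, median -0.50) past the threshold, and with an estimated correlation and no block these 4 had 0.836, 0.690, 0.836 and 0.422. The mean shift of glucocorticoid receptor targets was 0.56 on slide 3 and 0.55 on slide 4, and that of immediate early genes 0.41 and 1.08. No gene passed with limma (0 of 24739, also 0 with slide as a block), and 726 had an unadjusted p under 0.05. Among genes that did not pass were the brain proteoglycan Ncan (2.63 ± 0.53, adjusted p = 0.71), Cirbp (-1.93 ± 0.40) and Tnfsf13b, the B cell factor BAFF (-3.13 ± 0.71). The vasodilator peptide gene Adm stood at -4.77 ± 1.32, Il1a at 0.83 ± 0.90 and Tnf at 0.84.

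The stress effect in TLR-DKO NAc gave 2 genes past the threshold with limma. Oaz3, an ornithine decarboxylase antizyme, was at least 3.86-fold higher after R-SDS (2.70 ± 0.40, adjusted p = 0.0171). In wild-type NAc it was higher after R-SDS too (1.89 ± 0.43) but did not pass there (adjusted p = 0.705), so its rise is not shown to be particular to TLR-DKO. Npm2, a histone chaperone of the oocyte, was lower (-3.77 ± 0.50, adjusted p = 0.0062) and well above background on 3 of 3 naive and 2 of 4 R-SDS arrays. Cell cycle genes were higher as a list, with 18 of 21 above 0 and a median of 0.34 (camera adjusted p = 0.0342, adjusted p = 0.142 with an estimated correlation), including the ribonucleotide reductase gene Rrm1 at 2.38 and the proliferation marker Mki67 at 1.25. Homeostatic microglia markers were lower, with 20 of 22 below 0 and a median of -0.23 (camera adjusted p = 0.0342, adjusted p = 0.759 with an estimated correlation), including the purine receptor P2ry13 at -0.25. Oxidative phosphorylation genes were lower, with 9 of 34 above 0 and a median of -0.27 (camera adjusted p = 0.0342, adjusted p = 0.50 with an estimated correlation), including the succinate dehydrogenase gene Sdha at -0.80 and Ndufb3, a subunit of complex I, at -0.48.

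In the 3 lists 0 members passed when adjusted over the list alone. With slide as a block the adjusted p was 0.0490, 0.0490 and 0.131, and cytokines and chemokines (15 of 20 above 0 and median 0.43 without the block) went from 0.0608 to 0.0490, and had 0.759 with an estimated correlation and no block. The mean shift on slides 3 and 4 was 0.54 and 0.56 for cell cycle, -0.19 and -0.20 for homeostatic and -0.12 and -0.26 for oxidative phosphorylation genes. Without naive replicate 2 the adjusted p was 0.19, 0.28 and 0.43, and 1, 3 and 3 of 7 fits without an array kept the call. Oaz3 and Npm2 both passed with slide as a block (adjusted p = 0.0283 and 0.00728). Oaz3 alone missed the threshold with quantile normalization (0.132, and 0.276 with normexp), median centring (0.0816) and array weights (0.0886). Both missed it with only the groups compared (0.473 and 0.65), only the region (0.523 each) and the replicate block (0.560 and 0.634). Oaz3 changed by 2.70 and 2.91 within slides 3 and 4 and Npm2 by -3.99 and -3.76. Without naive replicate 1 or 3, both missed the threshold (Oaz3 0.150 and 0.128, Npm2 0.0766 and 0.107). Without R-SDS replicates 2, 3 and 4 in turn, Oaz3 missed it (0.0974, 0.108 and 0.0806). In all, 753 genes had an unadjusted p under 0.05. Tlr4, Il1a and Tnf had values of 0.56 ± 0.51, 0.40 ± 0.84 and 0.34 ± 1.02.

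The interaction in NAc tested whether these effects differed between genotypes, which here too cannot be told apart from the susceptible and resilient labels. Npm2 had the smallest p, at -4.12 ± 0.74 (adjusted p = 0.387), and without TLR-DKO naive replicate 2 it passed (-4.95, adjusted p = 0.00140). Ifnb1, which encodes interferon beta, differed by 6.03 ± 1.66 and Tnfsf13b by 3.37 ± 0.97, and Cx3cr1 by -0.21 ± 0.47. In all, 0 genes passed with limma, also with slide as a block, and 624 had an unadjusted p under 0.05. Of the lists, 0 passed (smallest adjusted p 0.0521), with medians of 0.42 for cell cycle genes, -0.34 for ribosomal protein genes and -0.62 for astrocyte markers. With slide as a block 3 lists passed, namely ribosomal protein genes (adjusted p = 0.0138), cell cycle genes (0.0429) and immediate early genes (0.0429, median -0.52 without the block). With an estimated correlation and no block the adjusted p was 0.969, 0.138 and 0.969.

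The region interaction asked whether the stress effect in wild type differed between NAc and mPFC. Cytosolic ribosomal protein genes had a lower stress effect in NAc, with 3 of 40 above 0 and a median of -0.51 (camera adjusted p = 0.0143, and adjusted p = 0.887 with an estimated correlation). The shift was 0.11 among the arrays of scan day 1 and -1.39 among those of scan day 2. The call was lost with slide as a block (adjusted p = 0.105) and without wild-type mPFC naive replicate 3 (0.84). It was also lost without wild-type mPFC R-SDS replicate 3, the array that stands apart. Adjusted over the list alone 0 members passed. Msantd3 differed by -7.76 ± 1.32 (adjusted p = 0.21) and Hilpda by -9.24 ± 1.99. Cemip differed by -3.70 ± 0.86 and Dnajb4 by -3.75 ± 1.01. Among genes, 0 passed with limma, also with slide as a block, and 801 had an unadjusted p under 0.05.

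**Figure D2:**
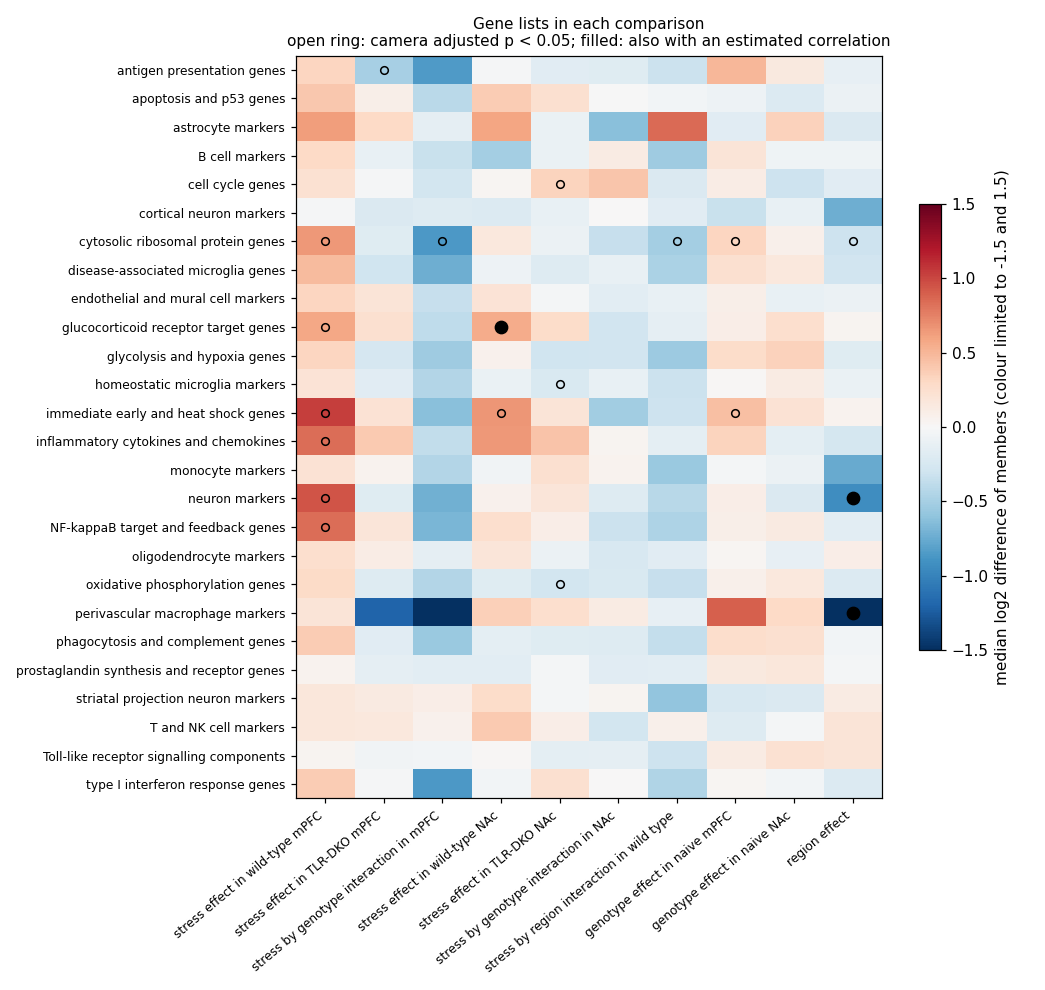
Median log2 change of each of the tested gene lists (rows) in each comparison (columns), with colour limited to 1.5 in either direction. An open ring marks a camera adjusted p under 0.05 and a filled mark one that also held with an estimated correlation, as for glucocorticoid receptor targets in wild-type NAc (median 0.56) and for perivascular macrophage markers (-2.06) and neuron markers (-0.93) between regions.

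The genotype effect in naive mPFC compares TLR-DKO with wild type before stress. Beside Tlr2, Lemd3, a protein of the inner nuclear membrane, was higher (2.21 ± 0.36, adjusted p = 0.0404), with 1 other probe at 3.05. The probe NAP060823-1, which the RefSeq table does not name and which was chosen after its values were seen, was lower in TLR-DKO (-3.28 ± 0.38, adjusted p = 3.90e-04). Immediate early genes were higher as a list (22 of 28 above 0, median 0.46, camera adjusted p = 0.0145, adjusted p = 0.742 with an estimated correlation), including Klf4 at 1.49, Atf3 at 1.39 and Jund at 1.02. Ribosomal protein genes were higher as well (37 of 40 above 0, median 0.32, camera adjusted p = 0.00169, adjusted p = 0.742 with an estimated correlation), including Rpl13 at 0.74. Perivascular macrophage markers had a median of 0.90, with 10 of 12 above 0 (adjusted p = 0.0776, 0.00165 with slide as a block, and 0.742 with an estimated correlation and no block).

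Adjusted over the list alone 0 members of these 2 lists passed. Immediate early genes shifted by -0.74 on slide 1 and 1.17 on slide 2, with an adjusted p of 0.167 with slide as a block, and ribosomal protein genes by 0.32 and 0.83 (7.49e-07). Without wild-type naive replicate 3 both calls were lost (0.37 and 0.83). In all 3 genes passed with limma, and 1407 had an unadjusted p under 0.05. Tlr2 differed by -5.71 with slide as a block (adjusted p = 3.09e-07) and by -5.42 and -6.31 within slides 1 and 2. Lemd3 was lost with slide as a block (2.09, adjusted p = 0.149) and without any single one of the 7 arrays (0.0696 to 0.290). It also missed the threshold with quantile normalization (0.0695, and 0.109 with normexp), no filter (0.0767), the mean of its probes (0.347), trend and robust (0.0582), array weights (0.184), only the groups compared (0.477), only the region (0.319) and the replicate block (0.651). It differed by 2.27 and 1.97 within slides 1 and 2. Genes that did not pass included the growth regulator Myc (1.33 ± 0.34), the integrin gene Itga9 (3.91 ± 0.96), Clec4n, a lectin receptor of myeloid cells (3.54 ± 0.92), the Fc receptor-like gene Fcrl1 (-4.05 ± 0.91) and the calcium-binding S100a11 (-4.87 ± 1.06), with adjusted p of 0.30 or more. Fcrl1 and S100a11 were not well above background on any naive TLR-DKO array, so they were at least 7.59-fold and 18.7-fold lower.

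The genotype effect in naive NAc gave 3 genes with limma, Tlr2, Npm2 and NAP060823-1. Npm2 was at least 11.7-fold higher in TLR-DKO (3.89 ± 0.54, adjusted p = 0.00358). This value and the stress effect and interaction of Npm2 in NAc all rest on the same TLR-DKO naive arrays, so they are not separate results. Its level there was -0.20 ± 1.50 (SD, n = 3), against -4.08 in naive wild type and -3.97 in TLR-DKO R-SDS samples. NAP060823-1 was lower, at -3.36 ± 0.41 (adjusted p = 7.74e-04). Npm2 passed with slide as a block (adjusted p = 0.00514) and Tlr2 differed by -5.83 (adjusted p = 2.85e-07). Within slides 3 and 4, Npm2 differed by 4.01 and 3.83 and Tlr2 by -5.82 and -5.84. Npm2 missed the threshold without wild-type naive replicate 2 (0.0501) or TLR-DKO naive replicate 1 (0.0547), with only the groups compared (0.789), only the region (0.385) and the replicate block (0.550). Among genes that did not pass were Ppp1r16b, a regulator of protein phosphatase (-4.66 ± 0.80, adjusted p = 0.0621), and the hair cell protein gene Whrn (-3.58 ± 0.81). Ppp1r16b was not well above background on any naive TLR-DKO array, so it was at least 9.90-fold lower. Of the lists, 0 passed (smallest adjusted p 0.0572, glucocorticoid receptor targets at a median of 0.25 and phagocytosis and complement genes at 0.24, both 0.0408 with slide as a block, and 0.186 and 0.762 with an estimated correlation and no block), and 816 genes had an unadjusted p under 0.05.

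The region effect compares 13 NAc with 13 mPFC arrays, averaged over genotype and condition. Perivascular macrophage markers, genes of the macrophages that line brain vessels, were lower in NAc in 12 of 12 members, with a median of -2.06 (camera adjusted p = 5.61e-09, and 0.0301 with an estimated correlation). F13a1, which encodes coagulation factor XIII A, had a log2 value of -5.48 ± 1.18, the mannose receptor gene Mrc1 -2.51 ± 0.94, Ms4a7 -2.38 ± 0.88 and the haemoglobin scavenger receptor gene Cd163 -1.74 ± 0.65. Cd163 was well above background on 0 of 13 NAc arrays, so its value is set against background there. Neuron markers were lower in 9 of 9 members (median -0.93, camera adjusted p = 0.00715, and 0.0301 with an estimated correlation), including the synaptic gene Syn1 at -1.38 ± 0.54 and the kinase gene Camk2a at -0.98. Cortical neuron markers had a median of -0.74 (adjusted p = 0.0844) and striatal projection neuron markers 0.12 (adjusted p = 0.673). Ribosomal protein genes were lower in 39 of 40 members (median -0.31, camera adjusted p = 8.19e-05, adjusted p = 0.710 with an estimated correlation), and homeostatic microglia markers had a median of -0.10.

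With scan day as a block the adjusted p was 1.09e-07 for perivascular macrophage markers, 0.00673 for neuron markers and 2.31e-05 for ribosomal protein genes, and disease-associated microglia genes passed too (0.0436, 19 of 21 below 0, median -0.34). With slide as a random block these had 0.0844, and 0.710 with an estimated correlation, and within scan days 1 and 2 it was 0.0151 and 0.836. Adjusted over the list alone 5 perivascular macrophage markers were lower, and 0 neuron and 0 ribosomal genes. Within scan days 1 and 2 the perivascular median was -1.90 and -1.78 (adjusted p = 1.48e-05 and 0.00163) and the neuron median -0.72 and -0.88 (adjusted p = 0.123 and 0.0206). Each scan day holds 1 slide of each region. The tests with scan day as a block or alone therefore count arrays of a slide as replicates and do not separate region from slide. No gene passed with limma and slide as a random block (0 of 24739), and 1421 had an unadjusted p under 0.05, 330 higher and 1091 lower. With scan day as a block instead, 441 genes passed, 46 higher and 395 lower, with F13a1 at -5.35 (adjusted p = 0.00741). Within scan days 1 and 2 it was 0 and 1 genes. Among genes that did not pass were the peptidase gene Naalad2 (4.35 ± 0.79, adjusted p = 0.15), the thyroid hormone binder Crym (3.54 ± 1.09), the cytokine receptor subunit Il6st (1.02 ± 0.31) and the axon guidance receptor Robo3 (-1.83 ± 0.30, adjusted p = 0.127).

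**Figure D3:**
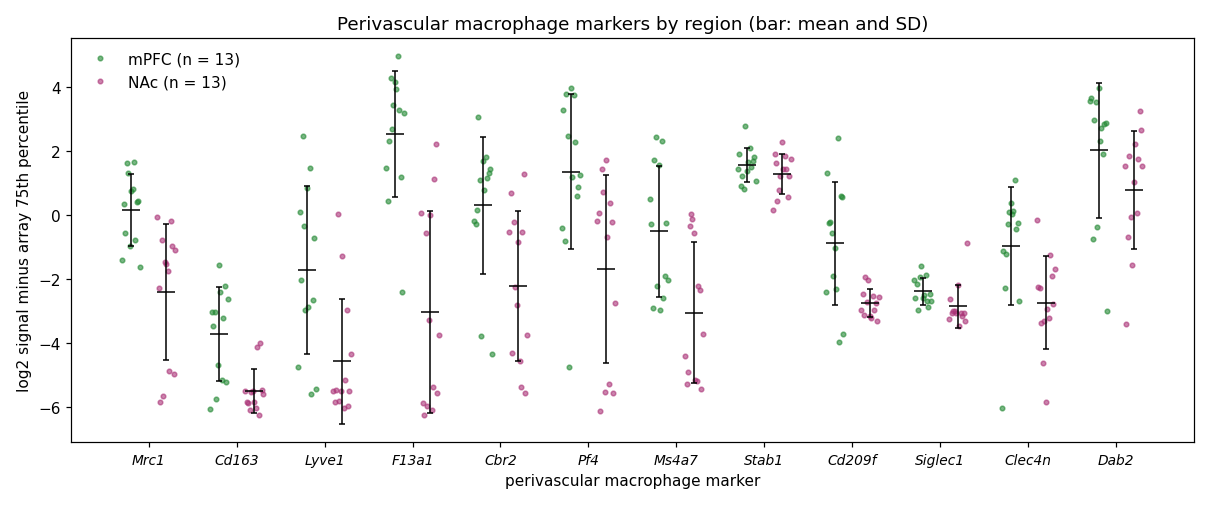
Log2 signal of 12 perivascular macrophage markers relative to the array's 75th percentile (y axis) in 13 mPFC and 13 NAc arrays, with 1 point per array and the mean and SD per region. F13a1 has a mean of 2.52 in mPFC and -3.03 in NAc, and Stab1 1.55 and 1.28.

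The stress effects of single genes were compared between strata that share no array. Across genes, which are not independent replicates, the log2 changes in wild type and TLR-DKO had a Pearson r of -0.01 (Spearman rho -0.02) in mPFC and 0.05 (0.05) in NAc. Between mPFC and NAc it was 0.08 (0.07) in wild type and 0.09 (0.09) in TLR-DKO. Changes had the same sign in 47.4%, 50.9%, 55.7% and 54.0% of genes in that order. The median SE of a stress effect was 0.61 in wild type and 0.57 in TLR-DKO. With such an SE, an r near 0 does not show that a shared response is absent.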

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

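Of the tests in this part, the test of genotype for ribosomal protein genes with an estimated correlation was chosen only after the result was seen, and so was the same test without R-SDS replicate 3. The splits within slides, the splits of the averaged effects and of the region effect with scan day as a block were added then too.

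Cytosolic ribosomal protein genes came up because their stress effect differed between genotypes in mPFC (mean difference -0.8396) and between regions in wild type (-0.4424). The mean score of the list was -0.12 ± 0.54 in naive and 0.54 ± 0.52 in R-SDS wild-type mPFC, and 0.19 ± 0.34 and 0.01 ± 0.34 in TLR-DKO mPFC (SD). A shift of all bright genes stays open. The list's median lay at percentile 0.03 of 100 among 10000 random lists matched on mean signal, of which 95% lay between -0.69 and -0.30. By the bound set in advance this would argue against such a shift. The random lists do not keep the way ribosomal protein genes vary together (estimated correlation 0.524), so their range is too narrow to decide. With normexp and quantile normalization the median difference was also smaller, as given above. The low-signal R-SDS replicate 3 array stays open as the cause. Without it the mean difference was -0.5411 (64.4% of the shift, adjusted p 2.698e-05), which met a bound set in advance to argue against it. That bound was wrong, because it rests on the preset correlation of 0.01, and with the correlation estimated without this array (0.507) the p was 0.223. The array is also the only wild-type R-SDS mPFC array on slide 2, where the list rose by 1.88, against 0.046 on slide 1, and between regions the call was lost without it (-0.1439, adjusted p 0.3217). Naive replicate 3, the only wild-type naive mPFC array on slide 2, stays open in the same way. Of the 13 fits of the mPFC interaction that left out a single array, the one without it had the largest camera adjusted p (0.0186). At the preset correlation the list passed in all 13. Genotype stays open too, because with an estimated correlation the p of the list was 0.1566, and the difference was -0.40 on slide 1 against -2.25 on slide 2. The difference could be a matter of a few arrays that share the slide, and no test here separates that from genotype. Nor can genotype be told apart from the outcome in the labels, susceptible in stressed wild type and resilient in stressed TLR-DKO mice.

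Among the TLR-DKO mPFC naive arrays, replicate 3 stood apart from the other 3 in its score of endothelial and mural cell markers (0.3503) and of oligodendrocyte markers (0.9594). Replicate 4 stood apart in its score of oxidative phosphorylation genes (-0.2694). In all, 66 groups of 4 values were examined and 3 lay past Dixon's critical value, where chance alone puts about 1 in 20 groups past it.

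Other splits of the same samples into groups of the same sizes were used to ask where chance can be excluded. The share of splits was under 0.05 for the 3 genes of the averaged stress effect (1 of 100, highest other 2). It was also under 0.05 for the 8 of the averaged genotype effect (1 of 100, highest other 1), which include the targeted gene Tlr2. Both averages were chosen after seeing the data, so these shares do not exclude chance. These counts rest on single arrays, with 0 to 11 and 3 to 16 genes when each array is left out in turn, and without the slide block they were 0 and 5. For the 2 genes of the stress effect in TLR-DKO NAc 1 of 35 splits was as large (highest other 1), but some of these splits move arrays of one group between slides, and the 18 that keep the slides are too few for a share under 0.05 (highest other 0). For the 441 genes of the region effect with scan day as a block, 1 of 100 splits of single arrays was as large (highest other 1), but each slide holds a single region and these splits break up the slides, so chance between slides is not excluded, and with slide as a random block 0 genes passed. For the genotype effect in naive mPFC the splits do not exclude chance for the count of 3 genes, since 2 of 35 splits gave as many. The other of these 2 follows the scan day and gave 5 genes, and with slide as a block Lemd3 was lost and Tlr2 kept (adjusted p = 3.09e-07). The count does not test each gene. Tlr2 and NAP060823-1 passed in each fit that left out a single array, and both passed in naive NAc too, so the doubt falls on Lemd3.

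For the comparisons of 3 against 3 samples, the 10 splits are too few for a share under 0.05. Stress in wild-type mPFC gave 2 genes against 1 in the highest other split (1 of 10) and 6 lists against 4 (1 of 10). Stress in wild-type NAc gave 2 lists against 3 (4 of 10), the 3 in the split by scan day. Glucocorticoid receptor targets and immediate early genes kept their call there with slide as a block. The genotype effect in naive NAc gave 3 genes against 1 (1 of 10).

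Every split reaches a count of 0, so the splits say nothing about chance for the results with 0 genes or lists. These are the genes of the stress effect in TLR-DKO mPFC (35 of 35 splits, highest other 4) and wild-type NAc (10 of 10, highest other 0), of the interactions in mPFC and NAc (100 of 100 and highest other 3 in each), of the region interaction and of the region effect (100 of 100 and highest other 2 in each). They are also the lists of the interaction in NAc (100 of 100, highest other 10) and of the genotype effect in naive NAc (10 of 10, highest other 4).

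For the remaining counts chance is not excluded. In TLR-DKO mPFC the stress effect gave 1 list (25 of 35 splits, highest other 7), and the split by scan day gave 2 genes and 4 lists. The interaction in mPFC gave 1 list (86 of 100, highest other 9). In TLR-DKO NAc the stress effect gave 3 lists (14 of 35, highest other 11), and the split by scan day gave 11 too. The region interaction gave 1 list (73 of 100, highest other 7), and the genotype effect in naive mPFC 2 lists (23 of 35, highest other 8). The region effect gave 3 lists (34 of 100, highest other 7). Splits that call several times the real number of lists point to a structure of the samples other than their groups, or to genes of a list that vary together (estimated correlation 0.524 for ribosomal protein genes, preset 0.01), and no test here separates these.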

How the results depend on the processing

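The values added after seeing the data were the averaged effects, scan day as a block or alone, the counts over named genes only, gMedianSignal in normexp and the fits without both outlying arrays. Results that answer a comparison kept their side of the threshold and their direction under 446 alternatives, passed it under 81, missed it under 108 and moved under 23, with 0 reversed. Single genes kept theirs under 6497, with 57 stronger, 169 weaker, 126 moved and 3 reversed, where a change of sign with an unadjusted p of 0.05 or more in both fits counts as moved. The cause of these changes was not tested, except that fewer arrays or genes leave less to test. Signal over background limits the values of dim genes.

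Genes past the threshold were as follows, each after its own number in the report. Counts of 0 within a single slide say nothing, since even Tlr2 missed the threshold there between naive genotypes. Stress in wild-type mPFC (2) gave 1 with normexp and quantile normalization, quantile normalization, median centring, every probe on its own, series matrix values or only the region. It gave 0 with only probes well above background on all arrays, only the groups compared, the replicate block or within slide 1 or slide 2. Stress in TLR-DKO mPFC (0) gave 2 with array weights, 1 with only the groups compared, 4 with only the region and 2 without both outlying arrays. The interaction in mPFC (0) gave 1 with array weights. Stress in TLR-DKO NAc (2) gave 1 with normexp and quantile normalization, quantile normalization, median centring or array weights. It gave 0 with only probes well above background on all arrays, only the groups compared, only the region, the replicate block or within slide 3 or slide 4. The region interaction (0) gave 1 with only the groups compared and 1 with the replicate block. Genotype in naive mPFC (3) gave 1 with only the groups compared, only the region or the replicate block and 0 within slide 1 or slide 2. Genotype in naive NAc (3) gave 1 with only probes well above background on all arrays or the replicate block and 0 with only the groups compared or within slide 3 or slide 4. The region effect (0) gave 441 with scan day as a block, 222 with no block, 199 with the replicate block, 4 with array weights and 1 within scan day 2. With an unadjusted p under 0.05 and 1.5-fold the counts were 1455, 1249, 1507, 725, 752, 624, 801, 1404, 813 and 1106 in the order of the report. Averaged stress (3) gave 0 with no block, 7 with normexp and quantile normalization and 16 with only probes well above background on all arrays. Averaged genotype (8) gave 5 with no block, 4 with quantile normalization and 3 with only probes well above background on all arrays.

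Gene lists past the threshold were 0, 0, 0, 1, 0, 0, 0, 0, 0 and 2 with an estimated correlation, against 6, 1, 1, 2, 3, 0, 1, 2, 0 and 3. With fry, stress in wild-type mPFC gave 3, in wild-type NAc 1, and in TLR-DKO mPFC, TLR-DKO NAc, the interaction in mPFC, the region interaction and genotype in naive mPFC 0. With normexp and quantile normalization, stress gave 4 in TLR-DKO mPFC, 5 in wild-type NAc and 1 in TLR-DKO NAc, and the region interaction 0. With no filter, stress gave 2 in wild-type mPFC and 5 in wild-type NAc, the interaction in NAc 3 and the region interaction 0. Slide as a block gave 5 for stress in TLR-DKO mPFC, 2 for the interaction in mPFC, 6 for stress in wild-type NAc, 3 for the interaction in NAc, 0 for the region interaction and 2 for genotype in naive NAc. The replicate block gave 2, 3 and 4 for the first 3 of these, 4 for genotype in naive mPFC and 3 in naive NAc. Without both outlying arrays, stress in TLR-DKO mPFC gave 0, the interaction in mPFC 5, the region interaction 0 and genotype in naive mPFC 4. The region effect gave 5 within scan day 1. Replicate numbers were not taken to pair the samples, since 4 of 18 correlations of same-numbered samples within a region were over 0.1 (-0.14 to 0.22). Between regions, in a check added after seeing the data, it was 7 of 12 (5.20e-04 to 0.24), and 11 of these pairs share a scan day.

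Leaving out each array in turn, genes ranged from 0 to 2, 0 to 2, 0 to 1, 0 to 0, 0 to 2, 0 to 1, 0 to 0, 2 to 4, 2 to 4 and 0 to 1, from 0 to 11 for averaged stress and from 3 to 16 for averaged genotype. Lists ranged from 2 to 8, 0 to 5, 1 to 7, 3 to 4, 0 to 6, 0 to 4, 0 to 2, 0 to 4, 0 to 4 and 3 to 4. The r between stress effects ranged from -0.0465 to 0.0777 between genotypes in mPFC, -0.00543 to 0.107 in NAc, and between regions 0.00457 to 0.12 in wild type and 0.0481 to 0.126 in TLR-DKO. With slide as a block it was 0.0548 between genotypes in mPFC and 0.10 in NAc, and in NAc 0.0839 with only probes well above background on all arrays. The Tlr2 difference ranged from -5.93 to -5.34, -6.18 to -5.45, -6.07 to -5.68 and -5.98 to -5.30, and Tlr4 from -0.0240 to 0.72, -0.0594 to 0.53, -0.53 to 0.21 and 0.03 to 0.75. Reversed were Rpl14 in the interaction in mPFC with the mean of the probes of a gene (0.01581), Zbtb16 after stress in wild-type NAc within slide 3 (-0.1357) and Tnf by genotype in naive mPFC within slide 1 (-2.62).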

Other observations

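In this part, the averaged effects, the scan day as a block or alone, the tests on the neighbours of Tlr2 and Tlr4, the split of the region calls by mean signal and the exact permutation tests of the 4 stress lists were chosen only after the result was seen.

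Averaged over both genotypes and regions, with slide as a block, 3 genes passed with limma for stress. Klf4, a transcription factor of the immediate early list, rose (1.92 ± 0.25, adjusted p = 0.00958), with values of 3.18, 0.48, 1.39 and 1.15 in wild-type mPFC, TLR-DKO mPFC, wild-type NAc and TLR-DKO NAc. Noct, a clock-controlled phosphatase, rose (3.24 ± 0.51, adjusted p = 0.0409), with 2.63, 4.72, 2.86 and 1.60. It was not well above background on any naive TLR-DKO mPFC array, so its value of 4.72 is set against background. Cirbp, the cold-inducible RNA-binding protein, fell (-1.21 ± 0.19, adjusted p = 0.0409), with 0.33, -1.99, -1.93 and -0.98, so that wild-type mPFC lay on the other side of 0. Ddit4 and Tsc22d3, both targets of the glucocorticoid receptor, stood at 1.73 ± 0.31 and 1.09 ± 0.20 (adjusted p = 0.065 each). In all, 1710 genes had an unadjusted p under 0.05, and without the block 0 passed. The count was 0 without TLR-DKO NAc naive replicate 1, 11 without wild-type mPFC R-SDS replicate 3, 8 without TLR-DKO NAc R-SDS replicate 4 and 5 without wild-type mPFC naive replicate 1. It was 1 without wild-type mPFC naive replicate 2 or R-SDS replicate 2, TLR-DKO mPFC naive replicate 1 or 3 or R-SDS replicate 1, wild-type NAc naive replicate 3 or R-SDS replicate 1, or TLR-DKO NAc naive replicate 3 or R-SDS replicate 3. Among lists, apoptosis and p53 genes had 16 of 21 members above 0 (adjusted p = 0.0259, and 0.20 with an estimated correlation), neuron markers a median of 0.37 (adjusted p = 0.0851) and homeostatic microglia markers -0.05 (adjusted p = 0.0945).

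Averaged over conditions and regions, with slide as a block, 8 genes passed for genotype, 1 higher and 7 lower in TLR-DKO, of which 6 are named. Beside Tlr2 (-5.76), these were Fcrls, an Fc receptor-like gene that marks microglia (-1.27 ± 0.14, adjusted p = 2.32e-04), Fcrl1 (-3.08 ± 0.46, adjusted p = 0.016), the nuclear receptor gene Rora (-1.72 ± 0.27, adjusted p = 0.029), Grxcr1 (-1.61 ± 0.27, adjusted p = 0.044) and the integrin gene Itga9 (2.27 ± 0.39, adjusted p = 0.049). In all, 2334 genes had an unadjusted p under 0.05, 5 passed without the block, 3 without TLR-DKO mPFC naive replicate 1, 16 without wild-type mPFC R-SDS replicate 2 and 4 or 5 without any of 16 other arrays, and 0 of the 26 lists passed.

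The hypothesis that 4 lists rise after stress in all strata together was tested by relabeling R-SDS and naive arrays within genotype, region and slide, in all 23328 ways. The exact two-sided permutation p was 6.001e-04 for immediate early genes (mean difference 0.76), 2.572e-04 for glucocorticoid receptor targets (0.40), 1.286e-04 for cytokines and chemokines (0.92) and 3.258e-03 for NF-kappaB targets and feedback genes (0.47), with adjusted p of 8.00e-04, 5.14e-04, 5.14e-04 and 0.00326. The difference was above 0 in 8, 8, 8 and 7 of 8 strata. The lists were found and tested on the same data, so a rise in both genotypes and regions remains a hypothesis.

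Fcrls and Fcrl1 lie 16 and 17 genes from Tlr2 on its chromosome, and both were lower in TLR-DKO. Sequence carried along with the knockout allele could account for this, and in the 200 genes around Tlr2 22 had a p under 0.05 (11%, 17 of them lower), a larger share than in 80.87% of other windows, which decides nothing. A variant under a single probe cannot be told apart from a lower level, since 0 other probes of either gene were kept. A response to loss of the receptors cannot be told apart either, because all 14 TLR-DKO arrays carry the allele and lack the receptor. Around Tlr4, 32 of 200 genes had a p under 0.05 (16%, 23 lower), a larger share than in 99.77% of 9721 other windows, which overlap and are not independent, and this value was seen before its test was written down.

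With scan day as a block, 395 of 441 genes called between regions were lower in NAc. Of the calls well above background on all arrays 90.24% were lower, a value set in advance to argue against a shift of dim probes between slides, but that bound was wrong, because the split leaves out every gene that fell below background in one region. Split by mean signal instead, 82.31% of calls lay among genes dimmer than the median, with 199, 164, 56 and 22 calls in 4 bins from the dimmest to the brightest. The median difference was -0.0467 over genes well above background on all arrays and -0.0860 over the others. Calls in the dimmest bin had a median of -0.945, so the bulk of dim genes moved far less than the calls. A shift of some dim genes stays open as a cause of the calls. Perivascular macrophages in the mPFC sort could account for a part, with at least 11 of 12 markers lower in NAc on each scan day. Of these 12 markers 2 are among the 441 calls, which were made over 24739 genes. Neurons or their debris in the sorts could account for another, with a median of neuron markers of -0.7175 or lower on each day, though the sort took EGFP-positive cells. Of neuron markers 0 of 9 were called and of cortical neuron markers 1 of 6, too few to speak against neurons. Called lower too were 1 astrocyte, 1 endothelial and mural cell and 1 erythroid marker. A difference between regions in the microglia themselves is not separated from these explanations by any test here.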
